A study of Mus musculus with 5 samples.

How the data were processed

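Germ cells were sorted by Oct4-EGFP fluorescence, a green reporter driven by the promoter of the germ cell and pluripotency gene Pou5f1 (Oct4), from the gonads of XY mouse embryos at E14.5. The cells of all XY embryos in a litter were combined into 1 sample, per the labels, so each array represents a separate litter. There were 3 samples of the strain C57BL/6J and 2 of 129S1/SvImJ. The strain names are those of the sample labels; the extraction protocol in the labels gives the substrain part of the second name as SvJ, so the substrain is not certain. Total RNA was amplified into biotin-labelled cRNA, per the labels' protocols, and hybridised to one-colour Illumina bead arrays carrying 25697 probes. The strain is the only factor in the labels. Litter and pool differ between all arrays, also within strains. The files name no collection day, slide or scan date, so any of these may coincide with strain.

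The main table holds mean bead intensity values on a linear scale, and per the file headers the authors applied neither normalization nor background subtraction to them. GenomeStudio is the tool named in the submitters' processing notes, and its version is not given in the sources used here. The same deposited table gives, for each probe and array, a detection p-value against the negative control beads, the count of beads, and a standard error over beads. The median bead count was 38 or 39 per probe, per the deposited table. A second deposited table of processed intensity values was compared with the first. On every array it was a linear function of the unnormalized signal, with a largest residual of 0.0138 intensity units. Its construction as background subtraction followed by scaling to 1 common mean is read from the values: 124 to 142 units had been removed per array, every array mean was 358.587, and 25.4% to 29.2% of the values were negative. The medians of the authors' processed intensity were 14.8, 11.5 and 11.5 in C57BL/6J and 12.6 and 13.5 in 129S1/SvImJ. This second table was used only as an alternative.

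Intensities were background corrected and quantile normalized with neqc of limma (version 3.58.1, R 4.3.3). The negative control level was inferred from the detection p-values, an offset of 16 was added, and log2 values were used throughout. Probes with a detection p below 0.01 on at least 2 arrays were kept, which left 10808. The strains were compared with lmFit and eBayes of limma, with no covariate. The Benjamini-Hochberg adjustment ran over all 10808 probes, with a threshold of 0.05. Differences are 129S1/SvImJ minus C57BL/6J on the log2 scale, where an offset of 16 makes folds of dim probes smaller than they were in the sample. Levels of different probes were not compared with each other. Where a probe was detected on no array of a strain, its fold is given as a bound ("at least"). The bound sets the mean of the brighter strain against the higher of the lowest detected value of each dim array and the dim probe's own value.

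Gene names came from the platform's annotation, updated through a gene table of assembly GRCm38.p6. Of the 25697 probes, 23978 had 1 gene symbol, none had several and 1719 were unnamed here. Symbols were the same in both sources, and 23962 probes matched the gene table. A gene was represented by its kept probe with the highest mean value, which gave 7557 genes, 1918 of them with several kept probes. In 7 genes, different probes passed the threshold in opposite directions: Ercc5, Mbp, Mrpl10, Pdxdc1, Pi4k2b, Stk35 and Usf1. No genome build is stated for the probes in the sources used here, so no probe coordinates are given. The order of genes along chromosomes, used near the end, came from the gene table.

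The 26 gene lists, holding 458 genes, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of the listed genes, 403 had a named probe and 257 were kept. Lists with at least 5 measured members (21) were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 21 lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list move on balance in 1 direction, and its mixed form whether they change in either direction. Named genes were of 3 kinds: up to 4 members of each list with the smallest adjusted p among those that passed, or the 1 member with the smallest p where none passed; the 10 largest differences in each direction among passing genes whose strains did not overlap, without provisional symbols; and a fixed set of 20 genes of germ cell fate and cell cycle, which included Nnt because C57BL/6J carries a deletion in it. Genes outside this rule that are named below were chosen after their values were seen.

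The test was tested on simulated data: arrays built from the means and spread of these 5 arrays. In 5 simulations of this comparison with 200 changed probes among 12571 to 13110 tested, 8.16% of 2-fold and 64.0% of 4-fold changes were recovered, all with the right sign, and 2.22% of calls were false. A simulated list of 20 genes shifted by -0.6 passed in 5 of 5 simulations and an unshifted one in 0 of 5. Noise was drawn separately for each probe, so these lists say nothing about the effect of correlation between members. In these simulations most 2-fold differences were therefore missed. The simulations held 200 changed probes, while 1532 probes passed in the real comparison, so the share missed there was not measured. The number of arrays limits the precision throughout.

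Alternatives changed the background correction, the normalization, the offset, the filter on dim probes, the variance model, the threshold, the choice of probe and the list test, and left out each array in turn. A block for the replicate number was also fitted. A fit to the authors' processed values with a floor of 1 was added after the data had been seen.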

Results

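Gene expression was measured in male fetal germ cells of a mouse strain labelled resistant to testicular teratoma, C57BL/6J, and of a strain labelled susceptible, 129S1/SvImJ. At E14.5, the age of all 5 samples, male germ cells are leaving the mitotic cycle and starting male differentiation. The comparison asks how the genetic background in which the RNA-binding protein DND1 acts differs in genes of cell cycle arrest, pluripotency and male fate. There were 3 C57BL/6J samples and 2 129S1/SvImJ samples, each from a separate litter. The arrays detected 8909, 10219 and 10426 of 25697 probes in C57BL/6J and 10478 and 10416 in 129S1/SvImJ. C57BL/6J replicate 1 was dimmer than the rest, with a mean intensity of 286 against 475 to 605 on the other arrays. Its median detected probe was 1.92 times as bright as its median undetected probe, against 2.53 to 3.01 elsewhere. Correlations across probes were 0.974 to 0.984 within C57BL/6J, 0.985 within 129S1/SvImJ and 0.923 to 0.961 between strains.

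In the 129S1/SvImJ samples, the DNA replication genes Mcm2, Mcm3 and Cdc6, the mitotic genes Kif11 and Cenpa, the Nodal antagonists Lefty1 and Lefty2, and the germ cell factors Tfap2c and Prdm14 were lower than in C57BL/6J. Nanos2, Dnmt3l and Piwil4, which act in male germ cell differentiation, were higher, while Piwil2 of the same list was lower. Of the cell cycle inhibitors Cdkn1c was higher and Cdkn2b lower, and the germ cell genes Alpl and Taf7l were higher. Of 9 measured markers of Sertoli cells, the supporting cells of the testis, 8 were also lower in the 129S1/SvImJ samples. In all, 1532 of 10808 probes differed, 792 higher and 740 lower in 129S1/SvImJ, and 1127 of 7557 genes, 613 higher and 514 lower (limma, adjusted p below 0.05). Of 21 gene lists tested, 6 passed camera, all as lower in 129S1/SvImJ; none of the 6 calls held with an estimated correlation, and fry, which asks whether members move on balance in 1 direction, passed only germ cell identity (adjusted p = 0.0201), with 0.0501 to 0.0509 for the 6 lists. The mixed form of fry, which asks for change in either direction, passed 20 of the 21 lists. The difference exceeded 4-fold in 42 higher and 52 lower genes. Without the dim array 1207 probes and 883 genes passed. Counts changed with the arrays used and with scaling, and 593 probes passed without C57BL/6J replicate 2. The split was 305 higher to 99 lower with median scaling and 734 to 431 on the authors' processed values with a floor of 16. Without either 129S1/SvImJ array, 1 array of that strain is left and the test is less sensitive. A lower count there, here and below, is therefore not by itself a smaller difference. The Sertoli cell median was -1.31 without 129S1/SvImJ replicate 1 and -1.25 without replicate 2, against -1.27 with all arrays. For DNA replication it was -0.71 and -0.52, against -0.59. List members that passed, added up over the tested lists, numbered 21 higher and 54 lower, against 14 and 7 with median scaling, 9 and 18 without C57BL/6J replicate 2, 5 and 11 (20 lists) without 129S1/SvImJ replicate 1, and 2 higher and 3 lower (20 lists) without 129S1/SvImJ replicate 2.

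**Figure D1:**
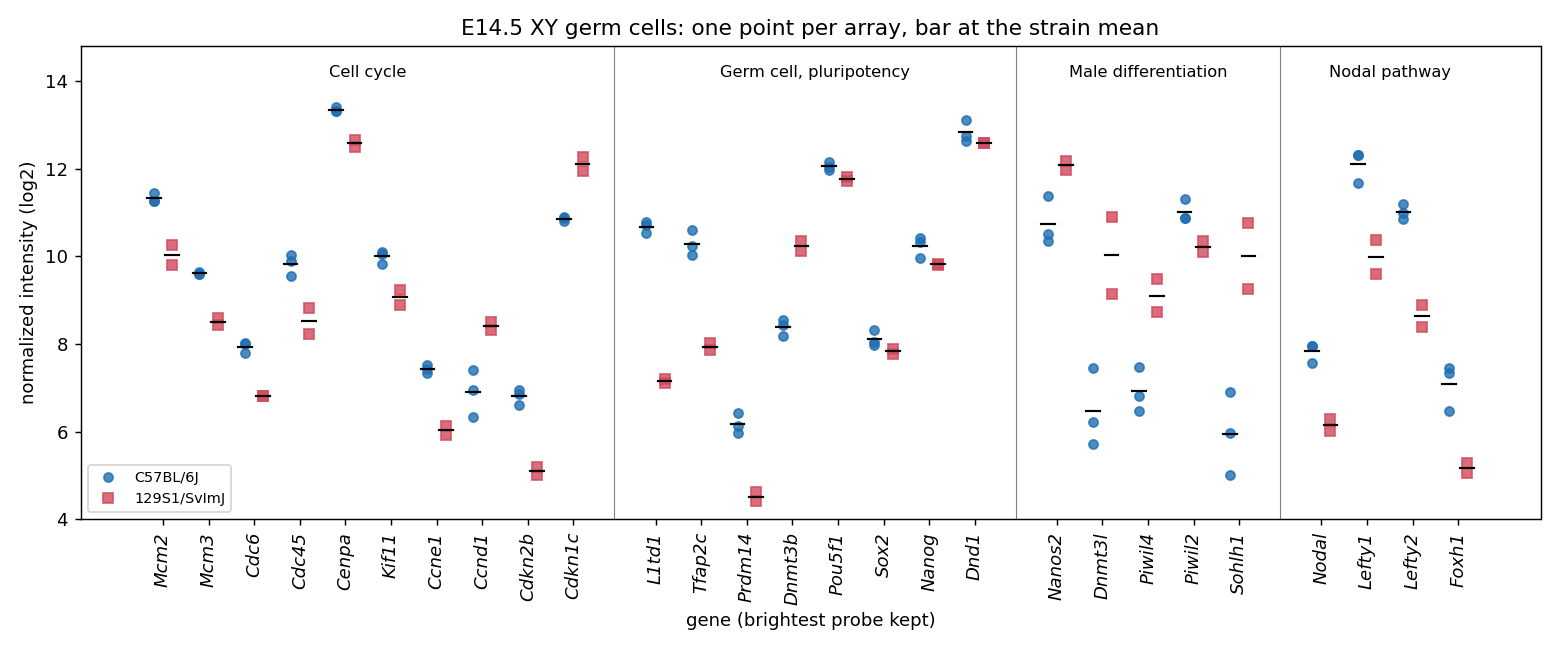
Normalized log2 intensity (vertical axis) of 27 named genes (horizontal axis), 1 point per array, blue circles for the 3 C57BL/6J arrays and red squares for the 2 129S1/SvImJ arrays, with black bars at strain means. Mcm2 fell from 11.33 in C57BL/6J to 10.04 in 129S1/SvImJ and L1td1 from 10.67 to 7.15, Dnmt3l rose from 6.47 to 10.02, and Pou5f1, Sox2, Nanog and Dnd1 did not pass the test.

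By the brightest probe of each gene and the rule for named genes, the largest increases in 129S1/SvImJ were in Sohlh1 and Gal. Dimmer probes such as those of Zfp330 (higher) and of Mcm6 and Mak16 (lower), given further below, differed more in log2 than any gene ranked here. Sohlh1 is a transcription factor of early spermatogonia, and Gal encodes the neuropeptide galanin. Sohlh1 was at 5.96 ± 0.95 (SD, n = 3) in C57BL/6J and 10.01 ± 1.05 (SD, n = 2) in 129S1/SvImJ, a log2 difference of 4.05 (SE 0.62, adjusted p = 0.0116), and its second probe gave 4.50. Gal went from 6.51 ± 0.29 (SD, n = 3) to 10.51 ± 0.21 (SD, n = 2; SE of the difference 0.22, adjusted p = 0.000433). Next came the channel gene Pkd2l1 at 3.83, Dnmt3l at 3.55, Nlrp14 at 3.46, the von Willebrand factor gene Vwf at 3.11, Stard3nl at 3.05, Tmem87a at 2.91, the calcium channel gene Cacna1h at 2.89 and Cd86 at 2.83. The largest decrease by the same rule was in Cops8, a subunit of the COP9 signalosome, at -4.51 (SE 0.22, adjusted p = 0.000357). Msc differed by -4.35. Ccl27a, Myo7a and Pou6f1 were detected on all C57BL/6J arrays and on no 129S1/SvImJ array, and were at least 12.7-fold, 11.7-fold and 9.52-fold lower. Khdc1c differed by -3.96, Copz2 by -3.74, Ipp by -3.58, L1td1 by -3.52 and Cd59a by -3.50. Of these 10 genes, only Ccl27a and Copz2 had further kept probes, which were lower in 129S1/SvImJ too (Ccl27a at least 2.54-fold; 3 probes of Copz2, at up to -3.65). Sohlh1 and Pkd2l1 were detected on 2 of 3 C57BL/6J arrays, the second Sohlh1 probe, Vwf and Cd86 on 1 of 3, and Cops8 and Msc on 1 of 2 129S1/SvImJ arrays, so the sizes of these differences rest on values near background.

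Some genes of DNA replication and mitosis fell in 129S1/SvImJ. Of 22 measured genes of DNA replication, 9 fell, none rose and 13 did not pass; 13 fell when adjusted over the list alone. The count of 9 became 0 with median scaling and without 129S1/SvImJ replicate 2, 1 without 129S1/SvImJ replicate 1, 3 without C57BL/6J replicate 2 and 4 without C57BL/6J replicate 1. The helicase subunit Mcm2 went from 11.33 ± 0.11 (SD, n = 3) to 10.04 ± 0.32 (SD, n = 2), a difference of -1.29 (SE 0.19, adjusted p = 0.0103). Mcm3 fell by 1.10, Cdc6, which loads the helicase, by 1.12, and Cdc45 by 1.30. Mcm6 fell by 0.72 on its brightest probe, with -0.96 on another and at least 71.5-fold lower on its last, which was detected on no 129S1/SvImJ array. The list's median difference was -0.59 (camera adjusted p = 1.28e-06; adjusted p = 0.446 with an estimated correlation). Of 18 genes of G2-M and mitosis, 6 fell and 1 rose, against 10 and 1 when adjusted over the list alone, with a median of -0.58 (camera adjusted p = 3.26e-05; adjusted p = 0.446 with an estimated correlation). The count of 6 became 1 with median scaling and without 129S1/SvImJ replicate 1, 0 without 129S1/SvImJ replicate 2 or C57BL/6J replicate 2, and 3 without C57BL/6J replicate 1. The spindle kinesin Kif11 fell by 0.93, the centromeric histone Cenpa by 0.77, the spindle factor Tpx2 by 0.99 and Kif23 by 0.87, while Anln, an actin-binding protein of cytokinesis, rose by 0.60. Sertoli cell markers were lower in the same 129S1/SvImJ samples, with a median of -1.27. With median scaling the median of all probes stood at 0.35 and those of these 2 lists at -0.22 and -0.20, and both lists passed camera under all 18 other settings of the data and fit.

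Among regulators of entry into S phase, inhibitors and activators each moved both ways. Of 11 measured inhibitors, Cdkn1c rose and Cdkn2b fell, against 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.747; adjusted p = 0.76 with an estimated correlation). Cdkn1c went from 10.86 ± 0.05 (SD, n = 3) to 12.10 ± 0.23 (SD, n = 2), a difference of 1.24 (SE 0.17, adjusted p = 0.00791). Cdkn2b was detected on no 129S1/SvImJ array and was at least 2.75-fold lower there (adjusted p = 0.00358). Cdkn1a differed by 0.22 (SE 0.17, adjusted p = 0.421), and its other 2 probes by -0.65 and -0.23. Of 10 activators, Ccne1 and Skp2 fell and Ccnd1 rose, in all genes tested and when adjusted over the list alone (camera adjusted p = 0.135). Cyclin E1, encoded by Ccne1, drives S phase entry; it differed by -1.40 (SE 0.16, adjusted p = 0.00526). Cyclin D1, encoded by Ccnd1, differed by 1.51 (SE 0.31, adjusted p = 0.0255), and its other 2 probes by 0.53 and 1.70. Skp2 fell by 0.73, and its other 2 probes gave -0.43 and -0.11. The inhibitor Cdkn1b, covered by 3 probes, was detected on no array. Without 129S1/SvImJ replicate 1, 1 inhibitor and 1 activator passed, both lower, and without 129S1/SvImJ replicate 2 none did; without C57BL/6J replicate 2 the activators numbered 0 higher and 1 lower, and without C57BL/6J replicate 3 the inhibitors 2 and 2.

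Germ cell identity genes went both ways. Of 14 measured, Alpl and Taf7l rose and Tfap2c, Prdm14 and Ifitm3 fell; adjusted over the list alone, 3 rose and 4 fell (camera adjusted p = 0.282). Tfap2c, a transcription factor of primordial germ cells, went from 10.29 ± 0.29 (SD, n = 3) to 7.94 ± 0.12 (SD, n = 2), a difference of -2.35 (SE 0.21, adjusted p = 0.00219), with -2.31 and -2.07 on its other 2 probes. Prdm14, which restrains somatic and epiblast programmes in the same cells, was detected on no 129S1/SvImJ array and was at least 1.77-fold lower (adjusted p = 0.0051). Ifitm3 differed by -1.27, Alpl, the tissue-nonspecific alkaline phosphatase, by 1.46 and Taf7l by 1.75. Dnd1 was at 12.83 ± 0.25 (SD, n = 3) and 12.58 ± 0.01 (SD, n = 2), a difference of -0.25 that did not pass (SE 0.19, adjusted p = 0.404). Nanos3 at 0.63 (adjusted p = 0.0564), Ddx4 at -0.90 (adjusted p = 0.0594) and Dazl at -0.26 (adjusted p = 0.303) did not pass either. The counts of 2 higher and 3 lower became 2 and 1 with median scaling, 1 and 3 without C57BL/6J replicate 2 or 129S1/SvImJ replicate 1, and 0 and 1 without 129S1/SvImJ replicate 2.

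Of 20 measured pluripotency genes, L1td1, Sox15 and Tcl1 fell and Dnmt3b and Nr5a2 rose; adjusted over the list alone, 5 fell and 2 rose. The counts of 3 lower and 2 higher became 1 and 1 with median scaling and without either 129S1/SvImJ array, and 2 and 1 without C57BL/6J replicate 2. Sertoli cell markers were lower in the same 129S1/SvImJ samples. L1td1, an RNA-binding protein of pluripotent cells, went from 10.67 ± 0.12 (SD, n = 3) to 7.15 ± 0.07 (SD, n = 2), a difference of -3.52 (SE 0.16, adjusted p = 0.000282). Sox15 was detected on no 129S1/SvImJ array and was at least 2.22-fold lower (adjusted p = 0.00632). Dnmt3b, a de novo DNA methyltransferase, rose by 1.86 and Nr5a2 by 0.90. The other Nr5a2 probe, detected on no C57BL/6J array, was at least 1.11-fold higher and did not pass. Sall4, also on the germ cell identity list, differed by -0.23 on its brightest probe and did not pass (adjusted p = 0.414). Another Sall4 probe, detected on every array, passed at -1.92 (adjusted p = 0.00284). Its last probe, detected on no 129S1/SvImJ array, was at least 1.21-fold lower and did not pass. The core factors did not pass: Pou5f1 differed by -0.29 (adjusted p = 0.232), Sox2 by -0.29 (adjusted p = 0.294) and Nanog by -0.42 (adjusted p = 0.18). With median scaling the signs of Pou5f1, Sox2 and Dnd1 turned, to 0.05, 0.13 and 0.01, with the median of all probes at 0.35. The list's median was -0.29 (camera adjusted p = 0.0493; adjusted p = 0.446 with an estimated correlation), and it failed camera in 7 of 18 other settings; with median scaling its median was 0.07, which lay 0.28 below that of all probes.

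The list of male germ cell differentiation did not pass. Of 14 measured members 3 rose, 1 fell and 10 did not pass, against 5 and 1 when adjusted over the list alone; the median was 0.39 (camera adjusted p = 0.135; adjusted p = 0.688 with an estimated correlation). Dnmt3l, a cofactor of de novo methylation in fetal male germ cells, went from 6.47 ± 0.89 (SD, n = 3) to 10.02 ± 1.24 (SD, n = 2), a difference of 3.55 (SE 0.64, adjusted p = 0.0189), with 4.08 on its other probe. Piwil4, a nuclear piRNA-binding protein, rose by 2.18 and Nanos2, an RNA-binding protein of male fate, by 1.33 (adjusted p = 0.0402). Piwil2, also a piRNA-binding protein, fell by 0.80. Of the C57BL/6J arrays, replicate 3 was highest for Dnmt3l (6.23, 5.72 and 7.45), Piwil4 (6.81, 6.47 and 7.47) and Nanos2 (10.36, 10.50 and 11.39). It was highest for Piwil2 too, at 11.31. The list lay at -0.19, -0.38 and 0.07 on the C57BL/6J arrays and at 0.10 and 0.28 on the 129S1/SvImJ arrays. Stage of development or the mixture of cells cannot be told apart from strain for this list either. The list passed as higher with median scaling (adjusted p = 0.00706) and without C57BL/6J replicate 3 (adjusted p = 0.0292), over a range of 0.00706 to 0.297 in the other settings. Its 3 higher members became 2 without C57BL/6J replicate 1, 1 without C57BL/6J replicate 2 or 129S1/SvImJ replicate 1, 4 without C57BL/6J replicate 3 and 0 without 129S1/SvImJ replicate 2; the 1 lower member passed in none of these. Of 16 genes of DNA methylation and chromatin, Dnmt3b, Dnmt3l and Ehmt2 rose and Hdac1 and Dnmt1 fell, in the same numbers when adjusted over the list alone (camera adjusted p = 0.822). Ehmt2, a histone methyltransferase, differed by 0.83 and the deacetylase Hdac1 by -1.24. In this list 1 higher and 0 lower passed without C57BL/6J replicate 2 or 129S1/SvImJ replicate 2, 2 and 0 without 129S1/SvImJ replicate 1, and 3 and 1 without C57BL/6J replicate 1 or replicate 3. Of 5 measured genes of teratoma susceptibility only Nanos2 passed, with 3 higher when adjusted over the list alone (camera adjusted p = 0.135); it kept that call only without C57BL/6J replicate 3 among the fits that left out 1 array. Dmrt1, with 1 probe, was detected on no array, and Kit, Bax and Mki67 were not analysed here.

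Of 10 measured genes of Nodal signalling, 5 fell in 129S1/SvImJ and none rose, and adjusted over the list alone 6 fell and 1 rose. The count of 5 became 3 with median scaling, 2 without 129S1/SvImJ replicate 1 and 1 without 129S1/SvImJ replicate 2. Sertoli cell markers were lower in the same 129S1/SvImJ samples, and within C57BL/6J both lists were lowest on replicate 3. Lefty2, a secreted Nodal antagonist, went from 11.01 ± 0.17 (SD, n = 3) to 8.64 ± 0.35 (SD, n = 2), a difference of -2.36 (SE 0.21, adjusted p = 0.00213). Its relative Lefty1 fell by 2.12 and Nodal itself by 1.68. Foxh1, which binds DNA with the SMAD proteins of the pathway, was detected on no 129S1/SvImJ array and was at least 3.33-fold lower (adjusted p = 0.0134). The fifth, Inhbb, was detected on no 129S1/SvImJ array, was at least 1.43-fold lower and is also on the list of Sertoli cell markers. The list's median was -0.67, or -0.55 with Foxh1 and Inhbb at their bounds, -0.34 with no background correction and -0.19 over 15 members with no filter on dim probes (camera adjusted p = 0.0125; adjusted p = 0.446 with an estimated correlation), and it did not pass among probes detected on all 5 arrays (adjusted p = 0.0881, over a range of 0.000103 to 0.0881 in the other settings). Of 8 genes of FGF and MAPK signalling, Etv5 fell by 0.80 and Fgf8 by 1.40, and 5 fell when adjusted over the list alone; the median was -0.63, or -0.39 with no background correction and -0.09 over 16 members with no filter on dim probes (camera adjusted p = 0.0493; adjusted p = 0.446 with an estimated correlation), and the list failed camera in 6 of 18 other settings. The count of 2 in the FGF list became 1 without C57BL/6J replicate 1, 4 without C57BL/6J replicate 3, and 0 with median scaling, without C57BL/6J replicate 2 or without either 129S1/SvImJ array. Of 8 genes of retinoic acid signalling, only the receptor gene Rarg rose, also when adjusted over the list alone; it was detected on no C57BL/6J array and was at least 1.70-fold higher in 129S1/SvImJ (camera adjusted p of the list = 0.135). No member of this list passed with median scaling or without either 129S1/SvImJ array.

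**Figure D2:**
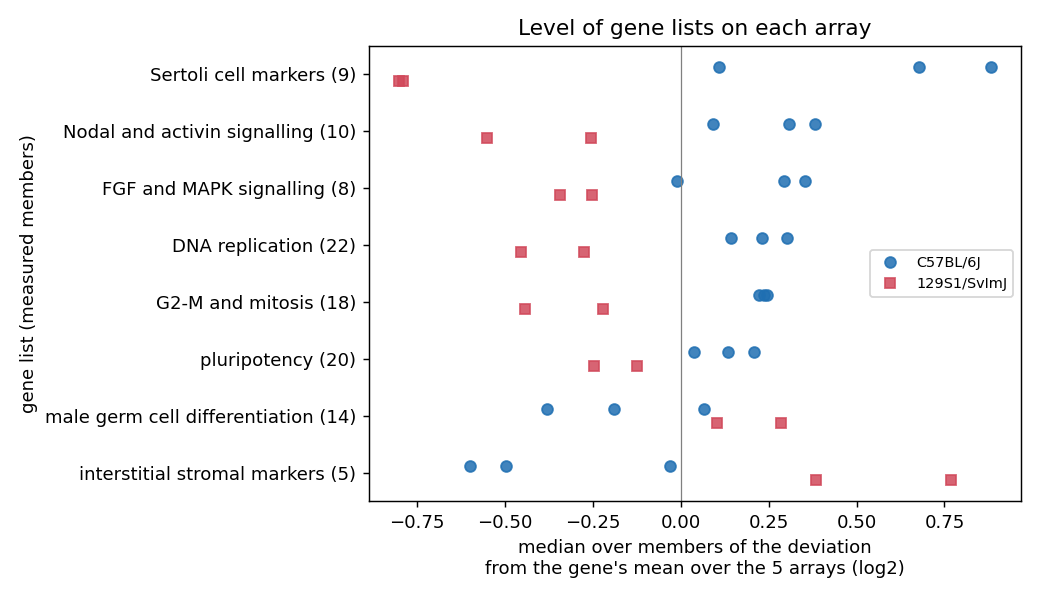
Level of 8 gene lists on each array: for each measured member, the deviation of its log2 intensity from its mean over the 5 arrays was taken, and the median over members is plotted (horizontal axis, log2; number of measured members in parentheses on the vertical axis; blue circles C57BL/6J, red squares 129S1/SvImJ). The Sertoli cell markers lay at 0.88, 0.68 and 0.11 on the C57BL/6J arrays and at -0.79 and -0.80 on the 129S1/SvImJ arrays, and the 5 stromal markers, of 17 with a probe, lay in the opposite order.

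Some markers of other gonadal cells differed between the strains as well. Of 9 measured Sertoli cell markers, 8 fell in 129S1/SvImJ and all 9 when adjusted over the list alone, with a median of -1.27, or -0.71 over 18 markers with no filter on dim probes and also with no background correction (camera adjusted p = 1.21e-05; adjusted p = 0.446 with an estimated correlation). The count of 8 became 1 with median scaling, 2 without C57BL/6J replicate 2 and 0 without either 129S1/SvImJ array. Clu went from 9.61 ± 0.72 (SD, n = 3) to 6.91 ± 0.22 (SD, n = 2), a difference of -2.70 (SE 0.40, adjusted p = 0.0103). The ligand gene Dhh fell by 1.23 and the tight junction gene Cldn11 fell by 1.59, and Ptgds was at least 1.63-fold lower. Of the 18 Sertoli cell markers with a probe, 9 were too dim to be kept, among them Sox9, Gata4, Nr5a1 and Fgf9. Of 5 measured interstitial stromal markers, Nr2f1 rose and was at least 1.27-fold higher, and 3 rose when adjusted over the list alone; the median was 1.16, or 0.88 with Nr2f1 at its bound (camera adjusted p = 0.0686; adjusted p = 0.446 with an estimated correlation). With no filter on dim probes the median over 17 stromal markers was 0.13 (adjusted p = 0.152, over a range of 0.0446 to 0.163 in the other settings). Of 4 endothelial markers Egfl7 rose by 0.60, with 0.07 on its other probe, and it was also the only 1 when adjusted over the list alone. Neither of 2 Leydig cell markers passed (Cyp11a1, at least 1.18-fold lower, adjusted p = 0.329) and neither of 2 erythroid genes (Hbb-y, 1.72, adjusted p = 0.145), with 0 in each when adjusted over the list alone. None of 12 macrophage markers with a probe was detected on 2 arrays. Xist, the transcript that silences an X chromosome, was detected on both 129S1/SvImJ arrays only, at least 1.28-fold higher, also when adjusted over the list alone, and the Y-linked genes Kdm5d at 0.08 and Eif2s3y at 0.00 did not pass. Nnt, covered by 3 probes, was detected on no array of either strain.

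Of 15 measured p53 targets, 5 fell and 1 rose, against 7 and 2 when adjusted over the list alone (camera adjusted p = 0.135). The 5 lower became 1 without C57BL/6J replicate 2, and 0 with median scaling and without either 129S1/SvImJ array. The cyclin gene Ccng1 fell by 1.08, Trp53inp1 by 0.84 and Gtse1 by 0.97, while Sesn1 rose by 1.26, each with other probes in the same direction. Of 13 apoptosis genes the death-promoting genes Bcl2l11 and Bbc3 fell by 0.80 and 1.40 and the caspase gene Casp9 rose by 1.09; the other probe of Bcl2l11 gave 0.25 and that of Casp9 -0.27. Adjusted over the list alone, 3 fell and 2 rose (camera adjusted p = 0.417), and none passed with median scaling or without C57BL/6J replicate 2. Of 14 imprinted genes Cdkn1c rose and Mest fell by 0.74, with -0.37 and 0.33 on the other Mest probes, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.282). Of 24 genes of oxidative phosphorylation Cox7a2 fell by 0.97, Ndufa1 fell by 0.66 and Ndufv1 rose by 0.55, and 2 fell when adjusted over the list alone (camera adjusted p = 0.138). Of 6 genes of the MHC and interferon response Isg15 rose by 1.02 and Ifitm3 fell, against 2 each way when adjusted over the list alone (camera adjusted p = 0.727). Of 11 immediate early and heat shock genes Junb fell and was at least 2.42-fold lower, against 4 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.282). None of 9 measured meiosis genes passed in either adjustment on its brightest probe (camera adjusted p = 0.536); Spo11 had the smallest p, at -0.77 (adjusted p = 0.0732), and its second probe passed in the opposite direction, at 2.70 (adjusted p = 0.00641). Without 129S1/SvImJ replicate 2 no member of the lists in this paragraph passed, and without 129S1/SvImJ replicate 1 only 1, lower, of the MHC and interferon list.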

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

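All alternatives here were chosen before the data were examined, except the authors' processed values with a floor of 1. Of the 1532 probes that differed, those tested in each of the 18 other settings of data and fit kept their sign in all of them. These probes were chosen on the same arrays, so a change of sign was unlikely from the start. The counts depended on the setting. Probes and genes numbered 2645 and 1916 at an adjusted p under 0.10, 2337 and 1730 with normexp without negative controls, 2516 and 1885 without background correction, and 2502 and 1865 with a variance trend and robust fit. They fell to 920 and 677 with no filter on dim probes, where more probes are tested. On the authors' processed values with a floor of 1 they were 395 and 287. With median scaling they were 404 and 309, and 365 of the 1532 probes were still called. That scaling set the arrays to 1 common median over all 25697 probes. Each array detected 34.7% to 40.8% of them, so this median lay among undetected probes. The 0.35 given as the median of all probes is over the 10808 kept ones. The cause of the lower counts was not tested. Leaving out 1 array gave 100 to 1703 probes, 73 to 1250 genes and 4 to 7 lists. The lowest counts came without 129S1/SvImJ replicate 2, where the lone array of the strain is assumed to vary like the others and fewer samples are tested. A block for the replicate number gave 1155 probes, 847 genes and 6 lists, of which 5 were lower: pluripotency no longer passed (adjusted p = 0.0637, over a range of 0.0175 to 0.186) and interstitial stromal markers passed as higher (adjusted p = 0.0446).

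Camera with an estimated correlation passed 0 of the 21 lists (6 with the preset correlation) and fry passed 1, germ cell identity; the cause was not tested. The DNA replication, G2-M and Sertoli cell lists passed camera in all 18 settings, Nodal signalling in 17, FGF signalling in 12 and pluripotency in 11.

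With median scaling the median of all probes was 0.35, and several small negative values turned positive, none past the threshold: germ cell identity 0.10, pluripotency 0.072, G1-S activators 0.0698, meiosis 0.16, apoptosis 0.29, p53 targets 0.13, oxidative phosphorylation 0.16, MHC and interferon response 0.25, immediate early and heat shock 0.29, Dnd1 0.0056, Pou5f1 0.0486 and Sox2 0.13. All of these lay below the median of all probes. On the authors' processed values immediate early and heat shock turned to 0.18 with either floor, and apoptosis to 0.041 with a floor of 1. DNA methylation and chromatin turned to -0.024 with no filter on dim probes, and G1-S inhibitors to -0.0329 among probes detected on all 5 arrays. Leaving out 1 array gave ranges that crossed 0: DNA methylation and chromatin -0.022 to 0.043, G1-S inhibitors -0.0159 to 0.18, apoptosis -0.14 to 0.0021, immediate early and heat shock -0.26 to 0.026 and meiosis -0.39 to 0.0169. The cause was not tested. Of the 83 named genes, 72 passed; 53 became weaker without 129S1/SvImJ replicate 2, 42 without 129S1/SvImJ replicate 1 and 40 with median scaling. Signal over background limits dim genes most on C57BL/6J replicate 1, at 1.92.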

Other observations

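All tests in this part were chosen after the result was seen, except the test of single probes near background. The lists of DNA replication, mitosis and Nodal signalling were lower in 129S1/SvImJ, with a median of -0.59 over 50 members, but none of the 3 passed with an estimated correlation (adjusted p = 0.446 for each). The dim C57BL/6J array is argued against as the cause, since 3 of the 3 lists passed without it at the preset correlation. Sertoli cells carried over in the C57BL/6J samples remain a candidate explanation. Across the C57BL/6J arrays the Sertoli markers lay at 0.88, 0.68 and 0.11 while the G2-M genes stayed at 0.24, 0.24 and 0.22. The other lists were lowest on replicate 3, as the Sertoli markers were. DNA replication lay at 0.30, 0.23 and 0.14 and Nodal signalling at 0.31, 0.38 and 0.09. With the mean Sertoli marker level as a covariate the median was -0.33 (G2-M -0.48 from -0.58, DNA replication -0.27 from -0.59, Nodal -0.22 from -0.67), and the standard error grew 2.57 times because that level follows the strains, so this and a strain difference in the germ cells cannot be told apart. The 129S1/SvImJ litters may also have been further along in development. The correlation between the strain difference and a difference between C57BL/6J litters had a median of 0.283 over 3 arrangements. It was 0.28 and 0.29 where the litter difference used replicate 3, and 0.05 between replicates 1 and 2. Replicate 3 also had the lowest Sertoli markers among the C57BL/6J arrays. The labels do not order the litters by age, so the correlation cannot decide, and development stays open. A difference between the strains themselves stays open and untested.

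Sertoli markers fell by 1.41 (SE 0.35) in mean level in 129S1/SvImJ, from 7.87 to 6.46. Fewer somatic cells of every kind stays open. The shift of the 5 measured stromal markers lay 2.31 (SE 0.51) above that of the Sertoli markers, but their mean of 5.27 in C57BL/6J was below the lowest detected value of each of its arrays (5.36 to 5.91), and the median over 17 stromal markers with no filter on dim probes was 0.13. Fewer Sertoli cells alone also stays a candidate explanation. Among the C57BL/6J arrays 9 of 9 markers were lowest on replicate 3, so they also moved together within a strain. Somatic cells of every kind varying together would give the same, so this cannot single out Sertoli cells. The sort on Oct4-EGFP should remove such cells, and lower transcription of these genes in the sorted cells stays open. Inhbb is on the Sertoli list and on the Nodal list.

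There were 16 genes with a probe differing over 4-fold and a second probe of mean log2 of at least 7. Of these, 9 (56.3%) had a difference not shared by the second probe. The share was 35.2% of 88 genes with differences of 2-fold to 4-fold and 31.4% of 121 genes with differences under 2-fold. Shared meant the same direction and at least a set part of the size. The probe with the largest difference of each gene was taken, so a smaller second value was likely from the start. The shares were not tested against each other. Mcm6 was at least 71.5-fold lower in 129S1/SvImJ on 1 probe and differed by -0.72 on its brightest, Mak16 was at least 17.3-fold lower and differed by 0.16, and Zfp330 was at least 22.6-fold higher and differed by 0.45. The test of a probe near background decides nothing: 9 of 9 were detected on every array of the brighter strain, but so were all 16 genes, since a difference over 4-fold needs a bright strain. In 5 of the 9 the probe was detected on no array of the dimmer strain. A strain variant under the probe may lower its signal; 6 of the 9 were lower in 129S1/SvImJ (exact binomial p = 0.508), too few genes to decide. The single-probe genes of the report share this limit.

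The 5 arrays can be split into 3 and 2 in 10 ways, and 1 of them, the real one, gave as many as 1532 probes; the highest other gave 0 by limma, with 1863 at an unadjusted p under 0.05 against 3499 for the real split. There are too few splits for a share under 0.05.

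Among 7553 measured genes in chromosome order, 188 adjacent pairs both passed, against a mean of 167 when genes were permuted (permutation p = 0.036). Pairs that both passed in the same direction numbered 134, against a permuted mean of 84.3 (permutation p = 1e-04, the smallest that 10000 permutations can give); this count also reflects the excess of pairs. They made up 71.3% of the 188, against 50.3% when permuted, a share that was not tested by itself. Genes that passed were unevenly spread over chromosomes (permutation p = 0.0251), from 11.5% on chromosome 11 to 19.8% on chromosome 4, apart from Y with 0 of 4 genes.

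Some probes differed between the 129S1/SvImJ arrays more than between strains. Plk1 was at 9.06 and 4.74 on them and at 10.38 to 10.73 in C57BL/6J, and Arv1 at 4.57 and 8.57. These and the following genes were chosen after their values were seen. Of the 5 measured X-linked Rhox homeobox genes, Rhox6 and Rhox9 were lower in 129S1/SvImJ (at least 2.66-fold, adjusted p = 0.00254, and -2.87, adjusted p = 0.00213), while Rhox1 at 0.19 (adjusted p = 0.644), Rhox5 at -0.05 and Rhox10 at 2.55 (adjusted p = 0.0673) did not pass. Nlrp5 fell by 1.72 (adjusted p = 0.00654), against the rise of Nlrp14, and Nlrp4c at -0.08 (adjusted p = 0.898) did not pass.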
